A study of Mus musculus with 2 samples.

How the data were processed

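Single cells of the mouse gut lamina propria were profiled in 2 libraries, CD163_NC and CD163_FL, with 1 library per group. The labels give the cells as CD45+, a surface protein of blood-derived cells, and the extract protocol names the colon as the source organ. Per the labels' protocols, cells were taken from the interphase of a Percoll density gradient, stained and sorted, dead cells were excluded with 7-AAD, and libraries were made with the 10x 3' kit V3. The series title names wild-type mice and mice deficient in CD163+ macrophages. No label says which library came from which mice, so the libraries keep their label names throughout and no genotype is assigned to either.

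The deposited values are counts of unique molecular identifiers (UMIs) per gene and cell barcode, not normalized. Per the file headers, the count matrices were written by Cell Ranger 7.1.0 and hold the barcodes called as cells. The submitters' processing notes name the mm10 build and Seurat 4, with no role given for Seurat. Alignment settings, the annotation release and any correction for free RNA are not given in the sources used here. Each matrix lists 32285 genes. CD163_NC held 10390 barcodes with 94729872 UMIs and CD163_FL held 15270 barcodes with 131306539 UMIs.

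Barcodes needed at least 500 UMIs, at least 200 detected genes and at most 10% mitochondrial UMIs. The UMI and gene minimum removed 8 barcodes of CD163_NC and 22 of CD163_FL, and the mitochondrial limit removed 370 and 869. Scrublet, run per library, called 334 doublets (3.22%) in CD163_NC and 780 (5.12%) in CD163_FL, below the 8.31% and 12.2% expected from the numbers of barcodes, so that some doublets will have stayed. Called doublets were removed, which took 333 and 769 further barcodes. Kept were 9679 cells of CD163_NC (median 6017 UMIs, 2150 genes, 1.92% mitochondrial UMIs) and 13610 cells of CD163_FL (median 6442 UMIs, 2264 genes, 2.50% mitochondrial UMIs).

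Cells of both libraries were clustered together in scanpy 1.11.5 under Python 3.11.15, with numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0 and python-igraph 0.11.9. UMIs were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 were used, with no integration of the libraries. Cd163, the sex-linked genes and the variable segments of immunoglobulins and T cell receptors took no part in clustering. The 28 clusters were named from 27 marker lists fixed before the data were examined. The scoring rule, the joining of 3 kinds of dendritic cell into 1 class and the exception for clusters led by granulocyte progenitor genes were set after the clusters were seen. A cluster took the name of a list within 0.5 (log2) of its best mean score that had the most markers among its 10 leading genes. It stayed unnamed when under 3 markers were detected in at least 10% of its cells, when another type had more markers among its leading genes, when progenitor genes were among them, or when its median UMI count was under 0.333 times that of its libraries and no marker was among its leading genes. That limit, also set after the clusters were seen, left named a macrophage-like cluster at 0.393 with no marker among its leading genes. This gave 17 named classes and 4 unnamed clusters. The names say only that a cluster is like a cell type.

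Shares of cells have exact binomial (Clopper-Pearson) 95% intervals, levels have exact Poisson 95% intervals, and ratios of levels have exact conditional binomial 95% intervals. Ratios of shares have log-normal 95% intervals. All of these cover counting error only. With 1 library per group no spread between animals can be had, so no test was made and no p-value is given, and every ratio compares these libraries, not the conditions. A count of 0 was read as allowing up to 3 counts.

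Gene levels were CPM from the summed UMIs of a class, in the 8 classes with at least 100 cells in each library. Log2 ratios are CD163_FL over CD163_NC. The 23 gene lists, with 328 entries, were fixed before the data were examined. For each list and class the median log2 ratio was taken over members with at least 20 UMIs. Members at or beyond 1.5-fold were counted each way. The median's percentile among 10000 random lists of the same size, matched on mean expression, describes where the list stood in these libraries. The rule for named genes asked for at least 50 UMIs in the higher library, a ratio interval outside 1.5-fold, and a level of at least 0.5 times that over all kept cells, to guard against free RNA. It left out mitochondrial, ribosomal, sex-linked and receptor segment genes and unnamed gene models. It took the 12 largest and 12 smallest ratios in macrophage-like cells and up to 4 each way in the other classes. Which class lists the text describes, how many list members it gives as examples, and the naming of Ccl2, Ccl7, Nos2 and Il6 were decided after the values were seen. Gene positions are from the GENCODE mouse release 21 annotation of mm10.

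For shares of cells with a UMI, each cell was thinned to 1000 UMIs. This left out 538 shallower cells of CD163_NC and 247 of CD163_FL. The gene step was tested on simulated data drawn from the macrophage-like cells over 32285 genes, with 50 genes changed at each fold. The rule for named genes picked 18% of genes changed 1.6-fold, 64% at 2-fold, 98% at 4-fold and 96% at 8-fold. The median recovered ratios were 1.60, 2.00, 3.96 and 7.64. Of 7541 unchanged genes over the UMI minimum, 0 were picked. A planted list had a median of 0.97 (log2) at percentile 100, and 0 of 18 unchanged lists passed both the size and the percentile. Both simulated libraries were Poisson draws from a single pooled profile, with no spread between cells or libraries. They also held no shared shift and no trend with gene span. The counts of 0 therefore cover counting error only, and false picks from other sources were not measured.

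Results were recomputed under 20 alternatives. The 14 fixed beforehand were mitochondrial limits of 20% and 5%, a minimum of 1000 UMIs and 500 genes, doublets kept, Leiden resolutions 0.5 and 2, principal components centred per library, thinned cells, median ratio scaling, means over cells, members with at least 5 or 100 UMIs, a named-gene rule at 2-fold, and subtraction of a free RNA profile. A further 6 were added after the data were examined: resolution 2 with monocyte-like clusters joined in, removal of the trend with gene span, subtraction of the median ratio of the other classes, leaving out subclusters led by other cell types, leaving out the macrophage-like cluster of low UMI count, and shares without the neutrophil-like, haemoglobin-led, Mpo-led, epithelial cell-like and fibroblast-like clusters. Harmony was not run. Centring did not mix the libraries: 22 of 31 clusters then drew over 80% of their cells from a single library, against 12 of 28 without it.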

Results

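The series set out to describe macrophages and other immune cells of the intestine in wild-type mice and in mice deficient in CD163+ macrophages. CD163 is a scavenger receptor for haemoglobin-haptoglobin complexes that marks subsets of tissue-resident macrophages. Kept were 9679 cells of the CD163_NC library and 13610 cells of the CD163_FL library, with 88444232 and 116757218 UMIs. Median depth was 6017 UMIs per cell in CD163_NC and 6442 in CD163_FL. There was 1 library per group, so every difference below has no replicate check, any difference in preparation falls together with the group, and intervals cover counting error only.

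Cd163 itself was close to undetected in both libraries. In macrophage-like cells, CD163_NC had 3 Cd163 UMIs, all in 1 of 565 cells (0.746 CPM, 95% Poisson interval 0.154 to 2.18), and CD163_FL had 0 UMIs in 1208 cells, which allows up to 0.394 CPM and up to 0.248% of cells with a UMI. The gene (ENSMUSG00000008845) lies on the plus strand of chromosome 6 from 124304656 to 124330527 in mm10. Over all kept cells, 10 cells of CD163_NC and 5 of CD163_FL had a UMI, at 0.170 and 0.0685 CPM. Among the CD4 T cell-like cells, which should lack the gene, 0 of 1736 and 0 of 2410 had a UMI, at median depths of 5472.5 and 6290 UMIs, against 6959 and 5657 in macrophage-like cells. Dendritic cell-like cells had 1 UMI in CD163_NC and 5 in CD163_FL. An unnamed cluster led by Mpo held 10 of the 15 Cd163 UMIs of CD163_NC. A difference in Cd163 between the macrophage-like cells of the libraries was not detectable at this depth, and the labels could not be checked against the gene. The sources used here do not say how the cells were depleted or whether the gene itself was altered.

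Macrophage-like cells made up a larger share of CD163_FL. They were 565 of 9679 cells in CD163_NC (5.84%, 5.38 to 6.32) and 1208 of 13610 in CD163_FL (8.88%, 8.40 to 9.37), a ratio of 1.52 (1.38 to 1.67). The class had 2 clusters, each with cells of both libraries. The larger, led by Cd14, Cxcl2 and Il1b, held most of the class in each library. The other, led by Plcb1, Fnip2 and App, had a median UMI count of 0.393 times that of its libraries, and without it the ratio was 1.25. The ratio rested on how finely cells were divided. At Leiden resolution 2 only a cluster led by C1qa, C1qb and C1qc kept the macrophage name and the ratio turned to 0.105, while the rest of the class became monocyte-like. The C1q-led cluster held 393 cells of CD163_NC and 58 of CD163_FL. Monocyte-like clusters held 151 and 21 cells of CD163_NC, and 491 and 662 of CD163_FL, so the libraries filled these clusters differently. The libraries were not integrated, so a different makeup of the class and a library-wide shift that splits clusters could not be told apart. With both names counted together at that resolution the ratio was 1.52.

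Transcripts of the first complement component C1q, which mature gut macrophages make in quantity, were found in fewer macrophage-like cells of CD163_FL. With each cell thinned to 1000 UMIs, C1qa (chromosome 4, 136895917 to 136898803, minus strand) had a UMI in 20.2% (16.9 to 23.8) of the class in CD163_NC and in 6.63% (5.27 to 8.22) in CD163_FL. Thinning left out 25 and 47 macrophage-like cells, and the unthinned shares were 28.5% and 14.7%. Thinned CD4 T cell-like cells gave 0.233% and 0.126% as background. For Il1b (chromosome 2, 129364570 to 129371139, minus strand), which encodes interleukin 1 beta, the thinned shares ran the other way, 58.0% (53.7 to 62.2) and 75.6% (73.0 to 78.1). Background in CD4 T cell-like cells was 0.874% and 1.93%, and the unthinned macrophage-like shares were 76.1% and 87.3%. As a share of all kept cells, cells with a C1qa UMI were 1.47% (1.23 to 1.73) of thinned CD163_NC and 0.651% (0.522 to 0.802) of thinned CD163_FL, and 3.07% and 1.95% unthinned. For C1qb these shares were closer, 1.56% (1.32 to 1.84) and 1.06% (0.896 to 1.25) thinned, with 0.349% and 0.294% in CD4 T cell-like cells, and 3.50% (3.15 to 3.89) and 3.32% (3.03 to 3.64) unthinned.

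Lymphoid and myeloid makeup differed widely between the libraries. CD163_FL held more CD8 T cell-like cells (18.5% against 7.11%, ratio 2.60), cycling cell-like cells (6.84% against 0.827%, ratio 8.28), dendritic cell-like cells (2.998% against 0.744%, ratio 4.03) and natural killer or type 1 innate lymphoid cell-like cells (1.80% against 0.351%, ratio 5.12). Gamma delta T cell-like cells (3.40% against 1.15%, ratio 2.97) and type 2 innate lymphoid cell-like cells (3.86% against 2.29%, ratio 1.69) were also more frequent in CD163_FL. CD163_NC held more B cell-like cells (20.0% against 8.86%, ratio 0.443), germinal center B cell-like cells (2.86% against 0.382%, ratio 0.134), neutrophil-like cells (1.83% against 0.0514%, ratio 0.0281) and epithelial cell-like cells (2.67% against 0.705%, ratio 0.265).

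Of the 17 named classes, 8 were at least 1.5-fold more frequent in CD163_FL, 4 were at least 1.5-fold less frequent and 5 lay within 1.5-fold. Within it were CD4 T cell-like cells at 17.9% and 17.7% (ratio 0.987), regulatory T cell-like cells at 1.13% and 0.801% (ratio 0.711), plasma cell-like cells at 18.5% and 12.7% (ratio 0.687), type 3 innate lymphoid cell-like cells at 0.920% and 1.20% (ratio 1.30) and mast cell-like cells at 0.434% and 0.492% (ratio 1.13). Fibroblast-like cells were 3 cells in CD163_NC and 61 in CD163_FL. Epithelial cell-like and fibroblast-like cells in a preparation labelled CD45+ lie outside that label, and the sort can set their shares. The 4 unnamed clusters held 15.4% of CD163_NC and 10.4% of CD163_FL. Without the neutrophil-like, haemoglobin-led, Mpo-led, epithelial cell-like and fibroblast-like clusters, the ratio was 1.38 for macrophage-like, 2.36 for CD8 T cell-like, 0.625 for plasma cell-like and 0.647 for regulatory T cell-like cells. On that base macrophage-like cells lay within 1.5-fold, and plasma cell-like and regulatory T cell-like cells lay beyond it, lower in CD163_FL.

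Several of these shares moved with the processing. The CD8 T cell-like ratio was 1.23 when thinned cells were clustered and 1.59 at resolution 0.5, and 98.7% of the cells of its larger cluster came from CD163_FL, so that library and type were not separable there. The gamma delta T cell-like ratio ranged from 1.62 to 5.18, the natural killer or type 1 innate lymphoid cell-like ratio reached down to 1.81, the cycling cell-like ratio was 4.02 and the regulatory T cell-like ratio 3.99 at resolution 2, and the fibroblast-like ratio was 1.99 with a minimum of 1000 UMIs. Independent of clusters, cells with a Cd8b1 UMI made up 3.38% (3.02 to 3.77) of thinned CD163_NC and 6.65% (6.24 to 7.09) of thinned CD163_FL, against 0.757% and 0.841% in CD4 T cell-like cells, and 8.999% and 21.4% unthinned.

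**Figure D1:**
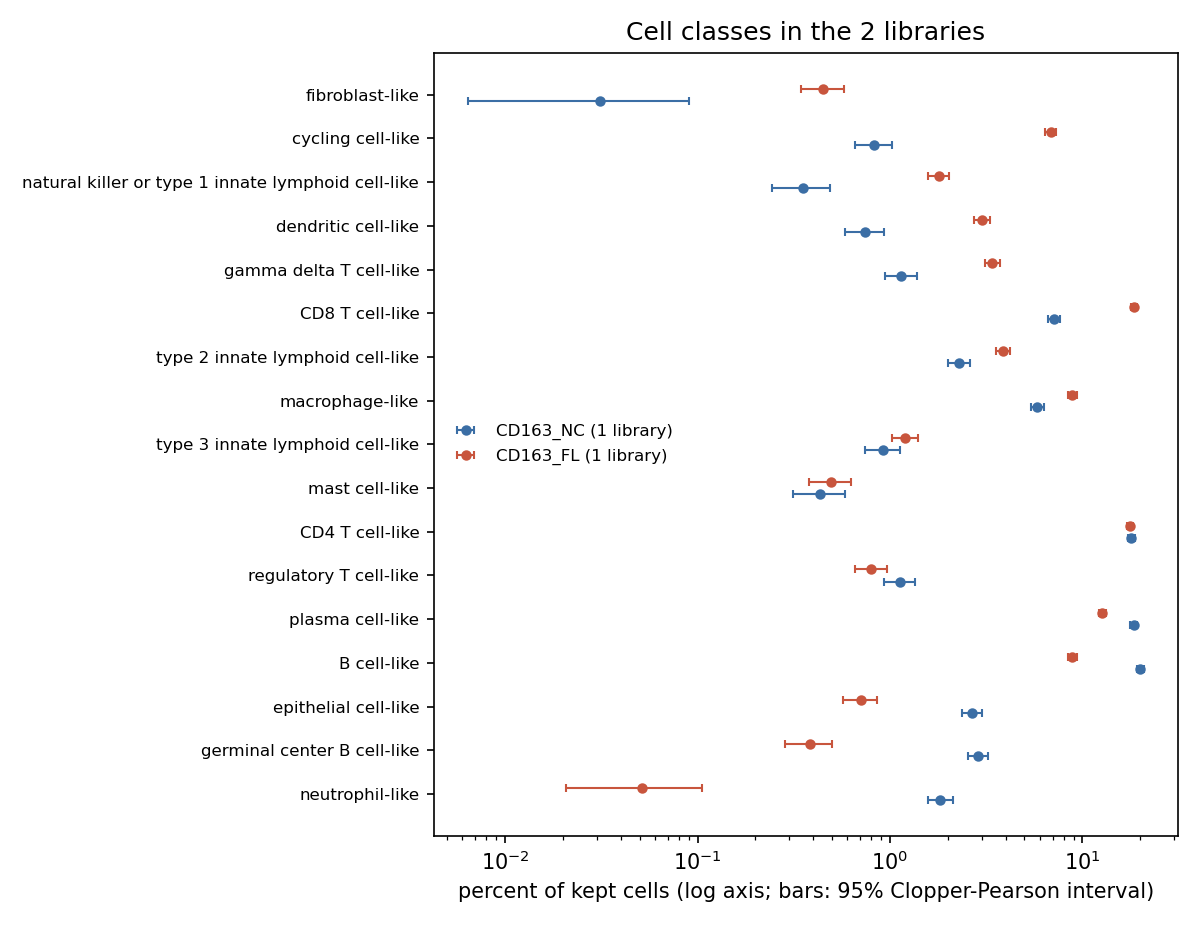
Share of kept cells (percent, log axis) of the 17 named cell classes in the CD163_NC and CD163_FL libraries, 1 library each, with 95% Clopper-Pearson intervals as bars. Cycling, dendritic and CD8 T cell-like cells took larger shares of CD163_FL, and neutrophil-like and B cell-like cells larger shares of CD163_NC.

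Within macrophage-like cells, genes of resident and mature gut macrophages stood lower in CD163_FL and genes of inflammatory cytokines stood higher. Of 10 measured members of the CD163 resident macrophage list, 9 were at least 1.5-fold lower and 1 was higher, with a median log2 ratio of -1.42 at percentile 0 of matched random lists. Mrc1, the mannose receptor, was at -1.60, the transcription factor Maf at -1.25 and the scavenger receptor Stab1 at -1.20, while F13a1, the A chain of coagulation factor XIII, was at 0.75. Of 19 measured members of the mature intestinal macrophage list, 14 were lower and 0 higher (median -1.22, percentile 0). Apoe was at -2.41 (2417 against 454 CPM), C1qa at -2.43 (837 against 156 CPM), C1qb at -1.93 and C1qc at -2.02. The median over all 11305 measured genes of the class was itself -0.29, by which median ratio scaling shifts every value.

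Of the 20 proinflammatory cytokine genes, 11 were at least 1.5-fold higher in CD163_FL, 2 were lower and 7 lay within (median 0.75, percentile 99.9). The neutrophil-attracting chemokine Cxcl2 was at 1.01 (4956 against 10013 CPM), Il1b at 1.18 (2410 against 5458 CPM), Ptgs2, the inducible cyclooxygenase, at 2.41 (619 against 3294 CPM) and the inflammasome sensor Nlrp3 at 0.98. Nos2, the inducible nitric oxide synthase, was at 1.85 and Il6 at 1.79. The members lower in CD163_FL were the monocyte-attracting chemokines Ccl2 at -1.24 and Ccl7 at -2.50. Of 15 monocyte-derived genes, 7 were lower and 3 higher (median -0.55, percentile 0.545), with Ly6c2 at -2.09, Ifitm3 at -1.13, Plac8 at -0.66 and the lectin receptor Clec4e at 1.80.

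These list values held for the class as a whole and were not seen in its C1q-led part. That part held 393 cells of CD163_NC and 58 of CD163_FL. It was marked out by C1qa, C1qb and C1qc themselves, so C1q ratios near 0 inside it are partly set by how it was formed. At resolution 2, where that part alone carried the macrophage name, the medians were -0.12 for CD163 resident, -0.15 for mature intestinal macrophage and -0.04 for proinflammatory cytokine genes, and C1qa was at -0.43, C1qb at -0.11, C1qc at -0.14, Mrc1 at 0.14, Maf at -0.14, Cxcl2 at -0.16, Il6 at 0.36, Ccl2 at 0.05 and Ccl7 at 0.12. Outside the class, the CD163 resident list was also lower in plasma cell-like cells, with 4 of 5 measured members lower (median -1.31, percentile 0.915). In the other 7 classes the proinflammatory list had medians from -0.78 in regulatory T cell-like cells to 1.55 in plasma cell-like cells. Neither end was stable, with 0.23 for the first at resolution 2 and -0.41 for the other in thinned cells. For the 15 of the 20 members measured in enough of those classes the macrophage-like median was 0.68. Subtracting each gene's median ratio over those classes left -0.04, but UMIs of these genes in other cells can be free RNA of macrophage-like cells, so this difference does not separate a shift of those cells from spilled transcripts. On the same scale Il1b was at -0.65, Nlrp3 at -0.45, Ptgs2 at 0.17, Clec4e at -0.24, Ifitm3 at -0.06, Ly6c2 at -0.69 and Apoe at -0.84.

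Interferon-response genes split. Of 17 measured, 9 were lower in CD163_FL and 4 higher (median -0.77, percentile 0). Irf7, a transcription factor of the type I interferon response, was at -2.61 and Isg15 at -0.77, while the guanylate-binding proteins Gbp2 and Gbp5, which respond strongly to interferon gamma, were at 2.32 and 2.18. Less the ratios of the other classes, the list median was 0.34 and Irf7 was at -0.86, and at resolution 2 Gbp5 was at 0.83. Of 14 complement and tissue support genes, 8 were lower and 1 higher (median -0.96, percentile 0.060), with C1qa and C1qb leading by UMIs, and the median was -0.09 at resolution 2. The 19 dissociation stress genes had 14 lower and 0 higher (median -1.11, percentile 0), with Junb at -0.98, Dusp1 at -0.76 and Jund at -0.68, and the median turned to 0.35 at resolution 2.

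Regulatory and anti-inflammatory genes had 4 of 12 members higher, 4 lower and a median of -0.12 (percentile 24.3). The checkpoint ligand Cd274 was at 1.66, the interleukin 1 receptor antagonist Il1rn at 1.47, Tnfaip3 at 0.82 and Zfp36, which destabilises cytokine mRNAs, at -1.06. Efferocytosis and lipid handling genes had 6 of 16 higher and 6 lower (median 0.22, percentile 92.1), with Spp1, which encodes osteopontin, at 2.61, the cholesterol exporter Abca1 at 1.29, Lgals3 at 0.60 and Apoe at -2.41. Scavenging and iron handling genes had 2 of 12 higher and 6 lower (median -0.39, percentile 9.98), with ferritin light chain Ftl1 at -0.74 and the scavenger receptor Msr1 at 0.77. Of 13 genes of antigen presentation by MHC class II, 2 were higher and 3 lower (median -0.27, percentile 20.2), with the protease Ctss at -0.77 and the costimulatory receptor Cd40 at 1.24. Several of these genes moved. At resolution 2 Il1rn turned to -0.25, Zfp36 to 0.07 and Msr1 to -0.06, and Tnfaip3 was at 0.17, Cd274 at 0.52, Abca1 at 0.50 and Cd40 at 0.20. Less the other classes Il1rn was at -0.70, Zfp36 at 0.36, Lgals3 at -0.37 and Spp1 at 0.90, and the efferocytosis median at -0.37.

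Hypoxia and glycolysis genes had 2 of 15 higher and 3 lower (median -0.38, percentile 4.05), with Hif1a at 0.87 and Tpi1 at -0.77. Cell cycle genes had 1 of 13 higher and 8 lower (median -0.78, percentile 10.8), with the proliferation marker Mki67 at 0.76 and Stmn1 at -0.91, and their median was 0.33 with doublets kept. Cells of the cycling cell-like cluster, 80 in CD163_NC and 931 in CD163_FL, were classed apart, which can lower cell cycle ratios in macrophage-like cells. Lists of other cell types were measured in the same cells. Neutrophil granule and recruitment genes had a median of -2.14 (10 measured, 7 lower, percentile 0) although their members Cxcl2 and Il1b were higher. Epithelial and mucus genes had a median of -1.60 (8 of 8 lower, percentile 0.060), with Lypd8 at -3.14 and Krt8 at -1.45. Subtracting a free RNA profile turned these medians to 1.71 and 0.0020, and less the other classes Lypd8 was at 0.53, Krt8 at 0.08 and Tpi1 at 0.03. Immunoglobulin constant region genes, which plasma cells express, had a median of -0.78 (12 measured, 7 lower, percentile 0.470), with Igkc at -0.81 and Jchain at -0.75, and a median of 0.01 less the other classes.

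Lymphocyte lists in macrophage-like cells had few measured members. Type 17 cytokine genes had 4 of 5 higher (median 1.28, percentile 99.7), with the nuclear receptor Rora at 0.70 and the aryl hydrocarbon receptor Ahr at 1.28, and the median was 0.69 at resolution 2. Type 1 cytokine genes had 3 of 11 higher and 2 lower (median -0.10, percentile 75.4), with Stat4 at 0.77 and Il12rb2 at 0.64, and the median was 0.71 with doublets kept. Regulatory T cell genes had 3 of 11 higher and 2 lower (median 0.08, percentile 84.8), with the anti-inflammatory cytokine Il10 at 1.59. Type 2 cytokine genes had 2 of 4 higher (median 0.93, percentile 99.2), with the epidermal growth factor family member Areg at 2.15 and Il1rl1 at 1.28 from 5 and 23 UMIs, and free RNA subtraction gave a median of 0.16 and Il1rl1 at -0.63. Germinal center genes had 2 of 7 higher and 3 lower (median -0.05, percentile 74.9), with Basp1 at 1.61 and the death receptor Fas at 1.06. Of the 2 measured sex-linked genes (median 1.46, percentile 96.1), Xist was at 0.19 and Ddx3y had 2 and 25 UMIs, and the median was -0.08 at resolution 2. The erythrocyte list had no member with enough UMIs in this class, and over all kept cells its 4 measured members had a median of 1.81.

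Of the 20 lists with at least 5 measured members, 10 lay beyond 1.5-fold and outside the central 95% of random lists in macrophage-like cells, 2 higher and 8 lower in CD163_FL. With median ratio scaling these were 8, with 2 higher and 6 lower. The 8 lower lists before scaling included the neutrophil, epithelial and immunoglobulin lists, which belong to other cell types.

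**Figure D2:**
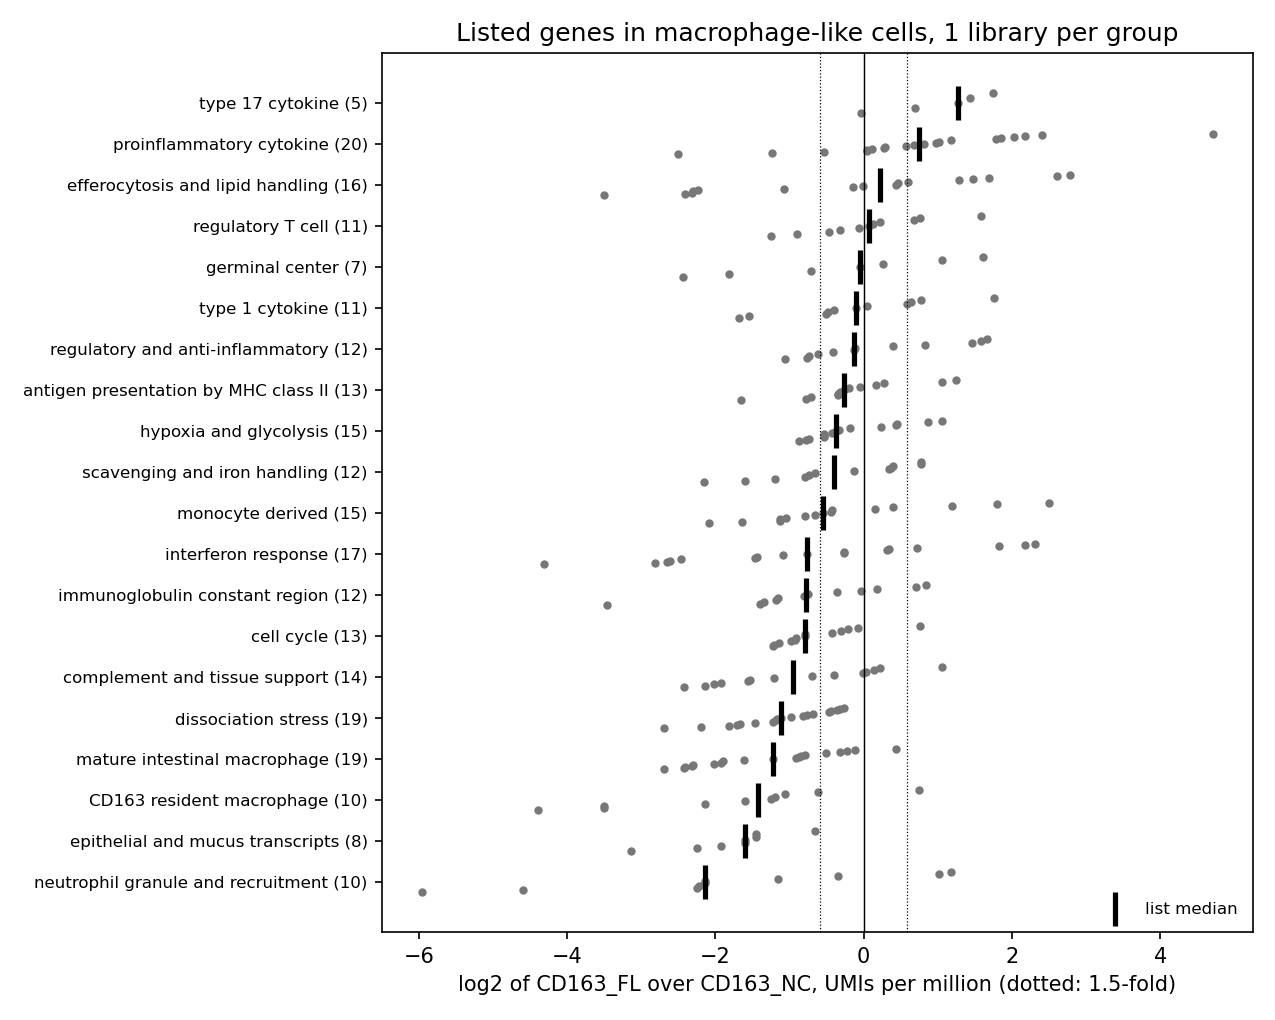
Log2 ratio of CD163_FL over CD163_NC (CPM) of each measured gene (points) of the lists with at least 5 measured members in macrophage-like cells, with list medians as bars, the number of members in brackets and dotted lines at 1.5-fold. Mature and CD163 resident macrophage genes lie mostly below 0, and type 17 and proinflammatory cytokine genes mostly above it.

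Single genes reached larger ratios than the lists. The neutrophil-attracting chemokine Cxcl3 (chromosome 5, 90786103 to 90789600, plus strand) had 23 UMIs in macrophage-like cells of CD163_NC and 1142 in CD163_FL, a ratio of 26.2 (17.4 to 41.5). Its log2 ratio of 4.71 was 1.19 less the median of the other classes, whose UMIs can be free RNA as well. The cationic amino acid transporter Slc7a2 had 24 and 1149 UMIs (log2 4.66), and Inhba, which encodes the activin A subunit, had 97 and 2486 (log2 3.76). Also higher were Il1f9 (4.42), the endothelin receptor Ednrb (4.08), Dcstamp (3.91), a protein of macrophage fusion, Dcbld2 (3.81), the serotonin receptor Htr2a (3.56), Il12a (3.54), which encodes the p35 subunit of interleukin 12, Plet1 (3.46), the antioxidant gene Srxn1 (3.45) and the macrophage elastase Mmp12 (3.44). Of these, Il1f9, Htr2a and Dcstamp had 3, 3 and 2 UMIs in CD163_NC.

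Among the genes with the lowest ratios, Ifit1bl1 had 78 UMIs in CD163_NC and 1 in CD163_FL, a log2 ratio of -7.21. Ifit3b was at -4.80 and Ifit3 (chromosome 19, 34583531 to 34588731, plus strand) at -4.31, with 440 and 42 UMIs, and at -1.03 less the median of the other classes. The chemokine Ccl8 (chromosome 11, 82115185 to 82116799, plus strand) had 222 and 20 UMIs (log2 -4.39), and Ccl12 was at -3.35. Siglec1, the sialoadhesin of tissue macrophages, was at -4.11, platelet factor 4 (Pf4) at -3.51, Ifi208 at -3.50, Lag3 at -3.47, Nfe2 at -3.47, Phf11a at -3.40 and Slc44a4 at -5.83. All 24 named genes also passed the rule at 2-fold.

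In thinned cells, Inhba had a UMI in 2.04% of macrophage-like cells of CD163_NC and 18.5% of CD163_FL (0 and 0.0841% in CD4 T cell-like cells, 7.08% and 40.1% of macrophage-like cells unthinned). The Cxcl3 shares were 0.556% and 8.27% (0 and 0.0841% in CD4 T cell-like cells, 1.77% and 16.9% unthinned). At resolution 2 Inhba turned to -1.21 and Nos2 to -1.37, Cxcl3 was at 2.25 and Pf4 at -0.21, and Ifit3 and Ccl8 stayed lower at -2.65 and -2.95. Others shrank there too, Slc44a4 to -1.07, Lag3 to -1.02, Siglec1 to -1.74, Ifit1bl1 to -2.88 and Srxn1 to 1.90, and in thinned cells Il1f9 was at 2.16 and Ednrb at 2.55. Some alternative moved 20 of the 24 named genes by over 1.5-fold. Ratios also followed gene length: the median log2 ratio was -0.61 over the measured genes of the shortest spans (lowest quartile) and 0.06 over those of the longest (highest quartile).

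Heterogeneity within macrophage-like cells could not be compared between the libraries by subcluster. Clustering them again gave 11 subclusters, of which 6 drew over 80% of their cells from a single library, so that library and subtype were not separable there. A further property of the division was that 3 subclusters were led by genes of other cells: immunoglobulin genes in the first, the T cell genes Camk4 and Cd28 in the next, and the B cell genes Ebf1, Cd79a and Pax5 in the last. Without these the macrophage-like ratio was 1.87 and the proinflammatory median 0.62.

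CD4 T cell-like cells of CD163_FL had lower interferon-response and stress genes. Of 17 interferon genes, 13 were lower and 1 higher (median -1.39, percentile 0), with Irf7 at -1.78, Isg15 at -1.07 and Gbp2 at 0.86. Of 19 stress genes, 13 were lower (median -1.31, percentile 0), with Fosb at -2.54, Junb at -1.62 and Jund at -0.83. Type 1 cytokine genes had 5 of 12 higher and 1 lower (median 0.38, percentile 98.9), with the interleukin 12 receptor chain Il12rb2 at 0.98, granzyme B (Gzmb) at 0.77 and the transcription factor Tbx21 at -1.23. Germinal center genes had 3 of 9 lower (median -0.43, percentile 3.12), the follicular helper T cell genes Cxcr5 at -2.52, Il21 at -2.43 and Bcl6 at -1.12. Type 17 genes had 6 of 10 lower and 2 higher (median -0.95, percentile 0.060), with Il1r1 at -1.24, Rora at 0.71 and Il17a at -0.65. The type 17 median was -0.12 and Il17a 3.36 when thinned cells were clustered, where the interferon median was -0.66, Irf7 was at -1.08, Junb at -0.91, Tbx21 at -0.25, Gzmb at 2.56 and Il21 at -1.83. The type 17 median was -0.23 at resolution 0.5, and Il17a was 2.16 at resolution 2.

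Different clusters held most of the CD4 T cell-like class in the libraries, led by Cd40lg, Maf and Ifng in CD163_NC and by Tnfrsf4, Cxcr6 and Prickle1 in CD163_FL. The genes with the largest ratios were Atp12a (5.74, from 1 and 86 UMIs), the purine receptor P2ry12 (3.31), Prickle1 (3.06) and Galnt3 (2.80). The smallest were Sostdc1 (-5.43), Fbn2 (-5.21), Ifit3b (-4.88) and Exoc3l2 (-4.52, but -2.11 with doublets kept). Some alternative moved 7 of these 8 by over 1.5-fold, with Atp12a at 4.59 after centring, Ifit3b at -4.03 with a minimum of 1000 UMIs, and Prickle1 at 2.03, P2ry12 at 2.72, Sostdc1 at -4.83 and Fbn2 at -4.61 at resolution 2.

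CD8 T cell-like cells of CD163_FL also had lower interferon-response and stress genes. Of 17 interferon genes, 14 were lower in CD163_FL (median -1.86, percentile 0), with Irf7 at -2.03, Isg15 at -1.95 and Irgm1 at -1.04. Of 19 stress genes, 15 were lower (median -1.57, percentile 0), with Fosb at -2.86, Junb at -2.37 and Jund at -1.14. Type 1 cytokine genes had a median of 0.02 (1 of 12 higher, 3 lower, percentile 30.2), with Ifng at -2.10, the chemokine Ccl5 at -0.72 and granzyme K (Gzmk) at 0.67. Regulatory T cell list genes had 8 of 11 higher and 3 lower (median 0.77, percentile 100), with the costimulator Icos at 1.39, the inhibitory receptor Ctla4 at 1.14 and Ikzf2 at 0.77. That median turned to -0.53, Ctla4 to -0.16 and Ikzf2 to -0.21 when thinned cells were clustered, where Icos was at 0.54, Irgm1 at -0.40 and Ccl5 at -0.10. A cluster led by Ccl5 and Cd8b1 held most of the class in CD163_NC and another, led by Cd8b1, Cd8a and Mctp2, in CD163_FL. Largest ratios were those of Mmp10 (4.24, from 1 and 92 UMIs, but 1.15 in thinned cells), Lhfpl2 (4.11, from 1 and 84), Pde5a (3.28) and Ankrd55 (3.07, but 2.07 at resolution 2), and smallest those of the interferon-induced genes Oas2 (-4.79), Oasl2 (-4.29), Slfn5 (-4.12) and Ifit3b (-4.11). Some alternative moved 5 of these 8 by over 1.5-fold.

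Type 2 innate lymphoid cell-like cells of CD163_FL had cytokine lists with higher medians, of sizes that depended on the processing. Type 2 genes had 5 of 9 higher and 0 lower (median 0.61, percentile 98.6), with Il5, an eosinophil growth factor, at 1.32, Areg at 0.74 and the interleukin 33 receptor Il1rl1 at 0.63. Type 1 genes had 5 of 8 higher and 0 lower (median 1.24, percentile 100), with Gzmb at 2.59, Tbx21 at 1.33 and Ccl5 at 1.15. This list was also higher over all kept cells (median 1.33), so free RNA or doublets of other cells can add to these values. Type 17 genes had 4 of 6 higher and 2 lower (median 0.68, percentile 98.8), with Il17a at 2.52, Rora at 0.76 and Csf2 at -0.75. Cell cycle genes had 6 of 10 lower (median -1.54, percentile 0), with Stmn1 at -2.93, Pclaf at -2.90 and Mcm5 at -2.34. The cycling cell-like cluster, with Pclaf and Stmn1 among its leading genes, was classed apart. It held 80 cells of CD163_NC and 931 of CD163_FL, so taking it out can lower these ratios, and they do not measure division. In thinned cells the cell cycle median was 0.02, the type 1 median 0.33, the type 2 median 0.30, Ccl5 0.33 and Gzmb 1.74, and the type 17 median was 0.53 over members with at least 5 UMIs. Proinflammatory genes had 9 of 14 higher and 2 lower (median 1.12, percentile 100, but 0.33 in thinned cells), and germinal center genes 4 of 5 higher and 1 lower (median 1.28, percentile 99.9, but 0.53 over members with at least 5 UMIs). The largest ratios were those of Akap12 (5.75, from 1 and 93 UMIs), Dscaml1 (3.95, from 3 and 80 UMIs) and Tnfsf8 (3.51, but 2.80 in thinned cells). Haemoglobin Hbb-bs, with 0 and 106 UMIs, was 20.5-fold higher with the 0 set to a floor of 3 counts (log2 4.35, and 3.65 as a mean over cells). The lower end of its interval was 16.3-fold. All 3 measured erythrocyte list genes were higher in this class (median 2.48, percentile 99.98). With doublets kept Tbx21 was at 0.40, Mcm5 at -1.22 and Dscaml1 at 3.36, and Pclaf was at -1.12 as a mean over cells. The smallest were Stmn1 (-1.03 with doublets kept), Slc6a13 (-2.55), Zfp593 (-2.46, but -1.72 with doublets kept) and Ifit1 (-2.23).

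Gamma delta T cell-like cells were led by Il23r, Zbtb16 and Il17a in the clustering, and the direction of their type 17 list was not stable. It had 3 of 10 genes higher in CD163_FL and 4 lower (median -0.02, percentile 35.7), with Rora at 0.87, Ahr at 0.79 and the epithelial repair cytokine Il22 at -1.49. Il22 turned to 0.23 at a mitochondrial limit of 5%, to 0.26 at a minimum of 1000 UMIs and to 0.18 at resolutions 0.5 and 2, where the list median lay between 0.67 and 0.78, while centring gave -0.57. Germinal center genes had 3 of 5 higher and 0 lower (median 0.85, percentile 99.2), with Pdcd1 at 1.08, Fas at 1.03 and Basp1 at 0.85, and Pdcd1 at 0.42 after centring. Proinflammatory genes had 7 of 11 higher and 3 lower (median 0.86, percentile 99.95), but a median of -0.49 over members with at least 100 UMIs. Immunoglobulin genes, which plasma cells and not T cells express, had 7 of 11 lower and 1 higher (median -0.84, percentile 0), and their UMIs here can be free RNA or doublets, with Igkc at -1.81, Jchain at -1.74 and Igha at -1.20. With doublets kept these were -0.68, -0.36 and -0.24, and over the alternatives the list median ranged from -1.77 to -0.50. The largest ratios were those of Cxcl3 (4.30, from 1 and 63 UMIs, 3.49 with centring), Chst2 (4.23, from 1 and 60, 2.28 with centring), Zfp180 (2.60, from 3 and 58, 1.45 with doublets kept) and Gpc1 (2.57, 0.99 with doublets kept), and the smallest those of Ifi27l2a (-2.75), Ifi206 (-2.23, -1.61 at a mitochondrial limit of 5%), Clnk (-2.20, -1.53 with a minimum of 1000 UMIs) and Fos (-2.09).

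Regulatory T cell-like cells, 109 in each library, differed little on their own list, with 2 of 13 genes higher, 3 lower and a median of -0.08 (percentile 26.9). Icos was at 0.63, Tigit at 0.59 and Tnfrsf18, the receptor GITR, at -0.66. The list median was -0.68 at resolution 2. The largest ratios were those of Lef1 (2.35), Vopp1 (2.30, 1.15 at resolution 2), Gnb4 (2.15, 0.92 at resolution 2) and the interleukin 18 receptor Il18r1 (2.04). The smallest were Adam12 (-2.66), Ddx60 (-2.58) and the immediate early genes Fos (-2.57) and Fosb (-2.35). Some alternative moved 7 of these 8 by over 1.5-fold. At resolution 2 Lef1 was at 1.62, Adam12 at -4.60, Ddx60 at -3.42 and Fos at -3.80, and Fosb was at -1.43 in thinned cells.

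Plasma cell-like cells of both libraries made mostly IgA. Igha was the dominant heavy chain in 91.1% (89.6 to 92.3) of these cells in CD163_NC and 87.1% (85.4 to 88.6) in CD163_FL, Ighg2c in 5.09% (4.12 to 6.21) and 6.31% (5.21 to 7.56), and Ighg2b in 3.02% (2.28 to 3.92) and 5.32% (4.31 to 6.49). The immunoglobulin list had 3 of 13 genes higher and 3 lower (median 0.10, percentile 72.9), with Ighg2b at 0.98 and the lambda chains Iglc2 at -0.95 and Iglc3 at -1.27. Interferon genes had 10 of 17 lower and 4 higher (median -1.21, percentile 0), with Isg15 at -1.92 and Gbp2 at 2.55, and the median was 0.09 in thinned cells. Largest were Mpzl2 (3.01), the stress-response gene Trib3 (2.63), Dgkb (2.57) and Gbp2. Dnah2 (-5.00, but -3.26 in thinned cells) and Ifi27l2a (-3.33) were lower in CD163_FL. Grm3 and Mei1, with 71 and 53 UMIs in CD163_NC and 0 in CD163_FL, had log2 ratios of -4.43 and -4.01 with the 0 set to 3 counts. The upper ends of their intervals were ratios of 0.0584 and 0.0790, and Mei1 was at -2.74 as a mean over cells and -5.71 with doublets kept.

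B cells present antigen on MHC class II and give rise to plasma cells. Stress genes in B cell-like cells had 6 of 19 lower in CD163_FL (median -0.45, percentile 0), with Fosb at -1.82, Jun at -1.51 and Egr1 at -0.85. Interferon genes had 8 of 17 lower and 2 higher (median -0.52, percentile 0.710), with Oasl2 at -2.23, Irf7 at -1.38 and Gbp2 at 0.95. Of 13 genes of antigen presentation by MHC class II, 2 were higher and 1 lower (median -0.09, percentile 5.80), with the costimulators Cd80 at 0.82 and Cd40 at 0.73 and the MHC class II transactivator Ciita at -0.71. Type 1 cytokine genes had 7 of 10 higher and 1 lower (median 0.69, percentile 100, and 1.24 with doublets kept), with Stat4 at 0.59, Tbx21 at 0.63 (0.18 with doublets kept) and Gzmb at 1.79 (1.19 in thinned cells). The same list had a median of 1.33 over all kept cells, and CD8 T cell-like cells were more frequent in CD163_FL. These UMIs in B cell-like cells can therefore be free RNA or doublets. Smpdl3b (2.39, but 0.94 as a mean over cells), Gab2 (2.21), Adm (2.18) and Zbtb46 (1.99, but 0.82 in thinned cells) had the largest ratios, and Pbld1 (-3.85, from 59 and 2 UMIs), Slc16a7 (-3.29), the surrogate light chain gene Vpreb1 (-3.19, from 56 and 3 UMIs) and Slfn5 (-2.83, but -2.09 in thinned cells) the smallest.

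Across these 7 other classes, 42 of 124 lists lay beyond 1.5-fold and outside the central 95% of random lists, 10 higher and 32 lower in CD163_FL, and with median ratio scaling 42, of which 11 were higher. The lower ones included the neutrophil, epithelial and immunoglobulin lists given next, which belong to other cell types. Their UMIs can be free RNA or doublets, and neutrophil-like and epithelial cell-like cells were more frequent in CD163_NC. The counts are therefore not counts of responses of the classes. Neutrophil genes were lower in the 6 classes with at least 5 measured members, with medians from -5.50 in CD8 T cell-like to -2.66 in plasma cell-like cells, but the gamma delta T cell-like median of -4.79 turned to 0.88 over members with at least 100 UMIs. In regulatory T cell-like cells the median was -2.40 over 4 genes and -0.25 in thinned cells. Epithelial genes were lower in the 4 classes with at least 5 measured members, from -1.80 in CD8 T cell-like to -1.05 in plasma cell-like cells. Immunoglobulin genes were also lower in CD4 T cell-like (median -0.72), CD8 T cell-like (-0.82) and regulatory T cell-like cells (-0.69), as were MHC class II genes in the first 2 of these (-0.61 and -0.69). Across genes, the log2 ratios of macrophage-like cells correlated with those of each of the 7 other classes (Spearman 0.362 to 0.499). The free RNA share, estimated from immunoglobulin UMIs in macrophage-like cells, was 8.88% in CD163_NC and 7.36% in CD163_FL. That class held an immunoglobulin-led subcluster, and without the subclusters led by other types the shares were 7.23% and 6.87%.

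**Figure D3:**
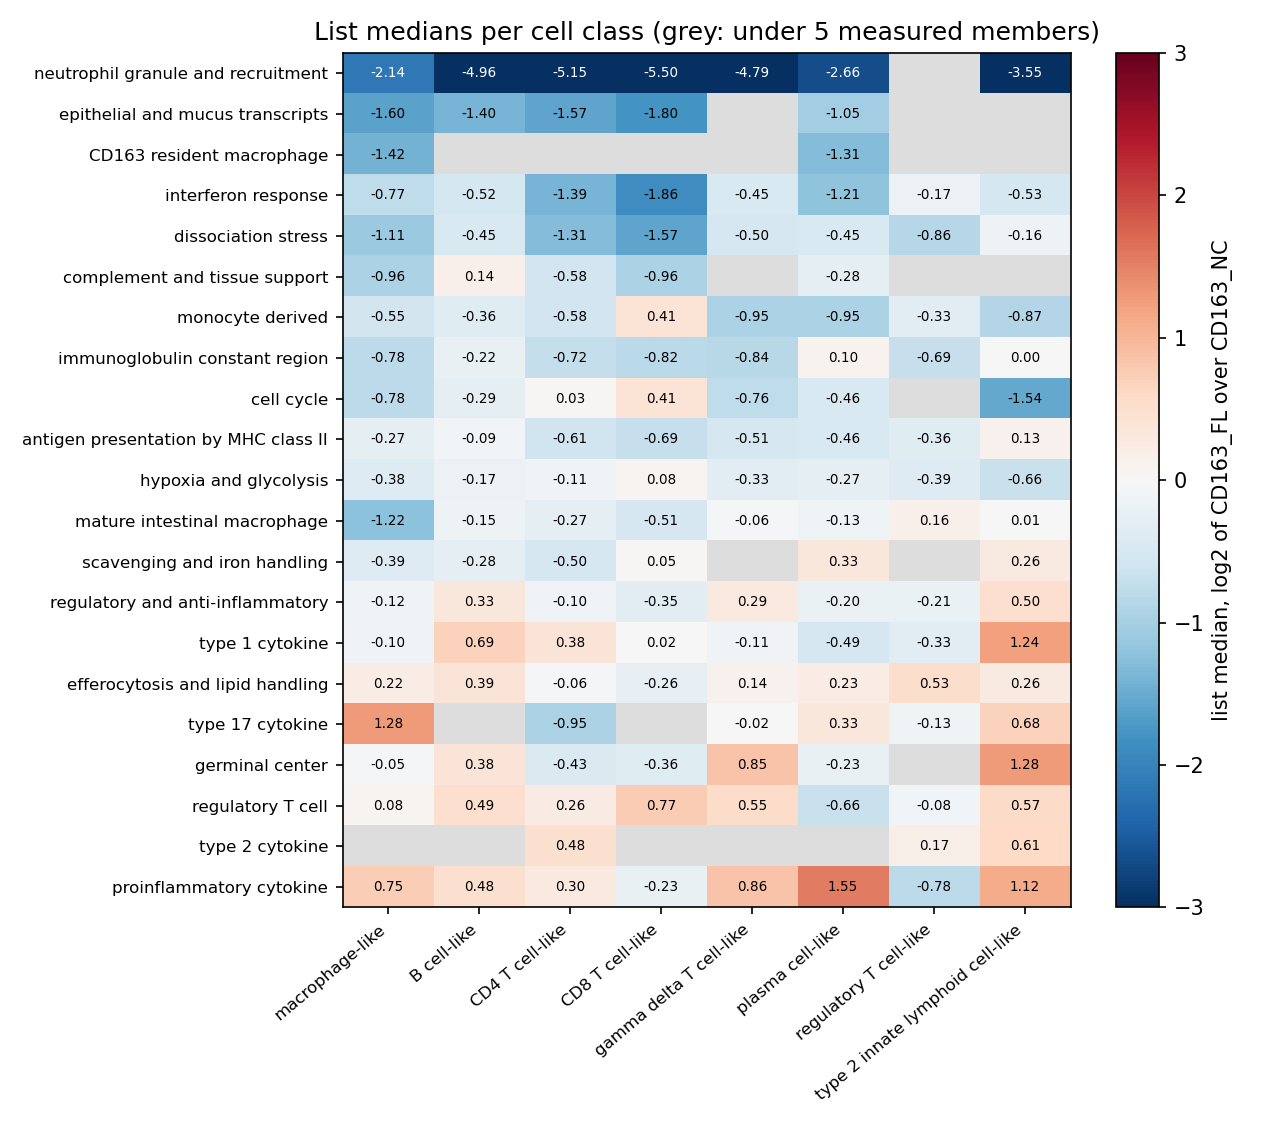
Median log2 ratio of CD163_FL over CD163_NC of each gene list (vertical axis) in the 8 cell classes with at least 100 cells per library (horizontal axis), 1 library per group, with grey for fewer than 5 measured members. Interferon-response and dissociation stress medians are below 0 in every class, from -1.86 to -0.17 and from -1.57 to -0.16.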

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

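The tests of cell isolation stress and of free RNA were chosen after their results were seen, and the other 5 tests below before theirs. The checks of whether C1q UMIs mark their cluster and of whether centring mixes the libraries were added after those tests' results were seen. A cluster led by the granulocyte precursor genes Mpo, Prtn3 and Elane drew attention as a signal outside the planned comparisons, with 0.940% of the kept cells of CD163_NC and 0.0294% of CD163_FL. Without the exception for progenitor genes, the naming rule would have called it plasmacytoid dendritic cell-like. It had 7 markers of that type detected, with Siglech and Cox6a2 among its leading genes. A haemoglobin-led cluster with low UMI counts (median 737.5) held 5.42% of CD163_NC and 0.845% of CD163_FL. It had 0 erythrocyte markers detected in at least 10% of its cells, so its name gives its leading genes and not a cell type. Lists that ran in opposite directions in different classes drew attention as well. Type 17 cytokine genes had a median of -0.95 over 10 measured genes in CD4 T cell-like cells and 1.28 over 5 in macrophage-like cells. The first was -0.12 in thinned cells and the other 0.69 at resolution 2. Proinflammatory cytokine genes had a median of -0.78 over 5 measured genes in regulatory T cell-like cells and 0.75 over 20 in macrophage-like cells, but at resolution 2 these were 0.23 and -0.04. The medians set against each other were thus not taken over the same genes. Whether these differences between classes exceed chance was not tested.

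Proinflammatory cytokine genes were higher in macrophage-like cells of CD163_FL, and 3 technical or compositional explanations were tested. A trend with gene length was removed, and the median rose from 0.75 to 1.01 (0.94 to 1.05). The shortest genes of the class had the lower ratios (median -0.61, against 0.06 for the longest). The trend thus ran against the pattern, and its removal says no more than that. Stress of cell isolation would have raised the stress genes, whose median was -1.11 (-1.19 to -0.97). Fewer C1q-expressing cells stay open: over the 349 and 917 cells without a C1q UMI the median was 0.92 (0.83 to 0.95), but 54.5% of the CD163_NC cells of the C1q-led cluster at resolution 2 had no such UMI either, so that this split does not separate the types, and inside that cluster the median was -0.04. Over the 15 of 20 members measured in other classes the median less those classes was -0.04, but UMIs there can be free RNA of macrophage-like cells, so a shift common to other cell types was neither shown nor excluded, and a difference between genotypes was not testable.

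CD8 T cell-like cells were more frequent in CD163_FL. A library-wide shift that splits clusters stays open: with principal components centred per library the ratio was 2.54 (2.34 to 2.75), but centring left the libraries more apart, with 81.1% of cells in clusters drawn over 80% from a single library against 33.8% without it, so that shift and cell number cannot be told apart. Differences in depth could have made the ratio, but the ratio of shares of thinned cells with a Cd8b1 UMI was 1.97 (1.73 to 2.23). Clusters of thinned cells gave only 1.23. Clustering thinned cells changes depth and class boundaries together, so the cause of this lower ratio could not be told apart. Variation between animals was not testable.

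Granulocyte progenitor transcripts were almost confined to CD163_NC, with 11694 and 37 Mpo UMIs and 11859 and 5 Elane UMIs. Bone marrow or blood-borne precursors in the preparation would bring B cell precursor genes as well, and these were 4.58 times as high in CD163_NC (4.35 to 4.82, from 6641 and 1913 UMIs), between the limits set beforehand, so these explanations cannot be told apart. Most of those UMIs were Vpreb3, with 5966 and 1846, while Dntt had 275 and 25, Vpreb1 226 and 42, Igll1 144 and 0 and Rag1 30 and 0, and these 4 together were 13.3 times as high (10.3 to 17.4), a subset chosen after the counts were seen. The Mpo-led cluster held 73.5% of the Dntt, 37.6% of the Vpreb1, 57.6% of the Igll1 and 70.0% of the Rag1 UMIs of CD163_NC, but 5.46% of Vpreb3. That cluster also carried plasmacytoid dendritic cell markers, so the cell type these UMIs came from was not determined. Vpreb3 lay mostly outside that cluster. B cell-like and germinal center B cell-like cells were more frequent in CD163_NC (ratios 0.443 and 0.134). The planned sum, mostly Vpreb3, can therefore follow B cell shares and could not decide on precursors. Free RNA spread over all droplets would leave little Mpo in a single cluster, but 80.8% (80.1 to 81.5) of the Mpo UMIs of CD163_NC lay in the Mpo-led cluster. Mpo was itself the gene that led this cluster, so its share there was partly set by the choice of cluster. The shares there were 90.6% for Ctsg, 78.0% for Prtn3 and 73.9% for Elane, which were also leading genes of the cluster and add no independent check. Mpo was among the leading genes of the low-UMI haemoglobin-led cluster as well. Some free Mpo RNA is therefore not excluded.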

How the results depend on the processing

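Of the 20 alternatives, 6 were added after the data were examined: joined monocyte-like clusters, span trend, ratios less the other classes, subclusters of other types, the low-UMI cluster and shares without 5 kinds of cluster. No paired analysis was possible because there was 1 library per group. Direction was kept in 140 of 147 values of 17 class shares, 1002 of 1069 list medians and 2347 of 2385 gene values. Reversals numbered 49 when the reported value, whatever the size of the turned one, had to lie beyond 1.5-fold to count. That rule was set after the results were seen. By the interval alone they numbered 82, of which 15 were among the 66 gene values under 20 UMIs. For every value below the cause was not tested. At resolution 2 the macrophage-like class had 393 cells of CD163_NC and 58 of CD163_FL, its share ratio was 0.105 and 4 macrophage gene lists passed. Medians there in macrophage-like cells were -0.12 for CD163 resident, -0.15 for mature intestinal, -0.037 for proinflammatory, -1.05 for interferon and 0.35 for stress genes, with Ccl2 at 0.052, Ccl7 at 0.12, Cxcl2 at -0.16, Dusp1 at 0.13, Il1rn at -0.25, Inhba at -1.21, Jund at 0.21, Mrc1 at 0.14, Msr1 at -0.063, Nos2 at -1.37 and Zfp36 at 0.074. Proinflammatory genes in regulatory T cell-like cells were at 0.23 and Il22 in gamma delta T cell-like cells at 0.18. Il22 was also at 0.18 at resolution 0.5, at 0.23 with a mitochondrial limit of 5% and at 0.26 with a minimum of 1000 UMIs and 500 genes. In thinned cells, Cd163 in macrophage-like cells of CD163_NC was 0 CPM, and medians were -1.15 for CD163 resident and -1.13 for interferon genes in macrophage-like cells, -0.53 for regulatory T cell genes in CD8 T cell-like cells (Ctla4 -0.16, Ikzf2 -0.21), 0.095 for interferon and -0.41 for proinflammatory genes in plasma cell-like cells, and 0.019 for cell cycle genes in type 2 innate lymphoid cell-like cells. In macrophage-like cells with doublets kept, medians were -0.93 for mature intestinal, 0.56 for proinflammatory, -0.90 for interferon and -0.95 for stress genes, and Stmn1 was at 0.084. Free RNA subtraction, whose share was read from immunoglobulin UMIs of the whole class, gave -1.20 for stress, 1.71 for neutrophil and 0.0020 for epithelial genes. With the span trend removed, CD163 resident genes were at -1.65, proinflammatory at 1.01, interferon at -0.42 and stress genes at -0.81. Less the other classes, 4 lists passed, and medians were -1.18 for CD163 resident, -0.042 for proinflammatory, 0.34 for interferon, 0.012 for immunoglobulin, -0.27 for stress, 1.53 for neutrophil and 0.31 for epithelial genes, with Clec4e at -0.24, Cxcl2 at -0.042, Dusp1 at 0.27, Igkc at 0.11, Il1b at -0.65, Il1rn at -0.70, Isg15 at 0.19, Krt8 at 0.081, Lypd8 at 0.53, Nlrp3 at -0.45, Tpi1 at 0.033 and Zfp36 at 0.36. Means over cells gave 0.51 for proinflammatory and -0.83 for interferon genes. Median ratio scaling gave -1.13 for CD163 resident, -0.93 for mature intestinal, 1.04 for proinflammatory, -0.48 for interferon and -0.81 for stress genes. Members with at least 100 UMIs gave -1.22 for CD163 resident genes and, in gamma delta T cell-like cells, -0.49 for proinflammatory, 0.88 for neutrophil and 0.20 for cell cycle genes, the last also at 0.26 with a minimum of 1000 UMIs and 500 genes. Without subclusters led by other types the share ratio was 1.87, proinflammatory genes were at 0.62 and interferon genes at -0.88. Without the low-UMI cluster the share ratio was 1.25, and CD163 resident genes were at -1.68, proinflammatory at 0.88 and interferon genes at -0.64. Depth limits Cd163, since 0 UMIs in 1208 cells, at a floor of 3 counts, still allows 0.394 CPM.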

Other observations

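No test was made for the values below. Over all kept cells, where cell makeup and expression act together, type 1 cytokine genes stood out as higher in CD163_FL, with 10 of 12 higher, 0 lower and a median log2 ratio of 1.33 (percentile 100). Among its members, the granule protease Gzmb was at 1.77 and the signalling factor Stat4 at 1.04. Regulatory T cell list genes had 7 of 14 higher, 1 lower and a median of 0.58, with Icos, a costimulator of activated T cells, at 1.74 and the inhibitory receptor Ctla4 at 0.96. Type 2 cytokine genes had 4 of 9 higher and a median of 0.50, with the interleukin 33 receptor Il1rl1 at 1.30. Type 17 cytokine genes had a median of 0.82, with Il17a (819 and 3381 UMIs) at 1.64 and Il17f at 2.16, although the list was lower within CD4 T cell-like cells. Proinflammatory cytokine genes had 13 of 20 higher and a median of 1.54. Germinal center genes ran the other way, with 8 of 12 lower and a median of -1.34, with Rgs13 at -2.60 and Il21 at -1.63.

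Haemoglobin genes had few UMIs in both libraries. Hbb-bs had 128 UMIs in CD163_NC and 820 in CD163_FL, Hba-a1 154 and 589, Hba-a2 108 and 606, and Hbb-bt 104 and 123, although the haemoglobin-led cluster made up a larger share of CD163_NC. Xist, which is transcribed from the inactive X chromosome of females, was at 718 CPM in CD163_NC and 748 CPM in CD163_FL. The Y-linked gene Ddx3y had 51 and 248 UMIs. The labels were not read against these values.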
